A study of Drosophila melanogaster with 20 samples.

How the data were processed

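Messenger RNA levels were measured in whole Drosophila melanogaster embryos at mid stage 13 on Affymetrix arrays, in 5 genotypes with 4 arrays each. The genotypes were a control, 3 alleles of mef2 with reduced activity (65, 424 and 113) and a mef2 null. Mef2 is a MADS-box transcription factor needed for muscle differentiation. Per the labels, the 3 hypomorphic alleles were induced in the stock that served as the control, which carries visible marker mutations, and the alleles rank by Mef2 level as control, 65, 424, 113 and null. Embryos came from collections of 30 minutes, were aged for 6.5 h at 25 °C, staged one by one and pooled in groups of 150. Mutant embryos were recognised by the absence of a GFP-marked balancer chromosome, per the labels' protocols. Nothing in the labels says that the 4 arrays of a genotype came from separate collections, so the p-values measure only the spread between these arrays, which may be technical.

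The deposited values are 1 intensity per probe set and array on a linear scale, computed by the authors with MAS5, per the submitters' processing notes. The MAS5 version and the genome build behind the array design are not given in the sources used here, so no coordinates are printed. The mean of each array after trimming 2% of values at each end was 100.02, so the deposited values had already been scaled to a common trimmed mean. They ranged from 0.0579 to 15800.4. Detection calls were not used here. The arrays' run records gave the hybridisation day, which was also the scan day, and the fluidics module.

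The arrays held 14010 probe sets. After 44 control probe sets were left out, 12442 probe sets had a single gene symbol, 327 had several and 1197 had none in the platform annotation, and no gene was named from a probe set with several. Of the single-symbol probe sets, 12393 matched the gene table of the RefSeq Release 6 assembly, which supplied current symbols and the chromosome of each gene. They stood for 10844 genes, of which 1209 had 2 or more probe sets. The probe set with the highest mean represented its gene. The probe sets in the lowest 25% by mean log2 value over all arrays, at a signal of about 9.29, were left out, which left 8357 genes. Mef2 itself had no named probe set here, so the targeted gene could not be checked. The same held for Mhc, Act57B, Tm1 and wupA, which encode major sarcomere proteins.

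Values were tested as log2(signal + 16). A fold change is therefore on the log2(value + pseudocount) scale and understates the change of genes with low signal. Where the mean signal of a group lay under the filter level of 9.29, the size of the change depends on the pseudocount. The log2 change of such a gene is given on the scale with a pseudocount of 16, without a linear fold, and the gene is named beside it. limma (version 3.58.1 in R 4.3.3) fitted 1 mean per genotype over all 20 arrays, with 15 residual degrees of freedom and a median of 8.55 prior degrees of freedom from eBayes with a mean-variance trend. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The contrasts were each allele against the control, the 3 steps between adjacent alleles, a linear trend over the activity rank, and, among the genes lower in the null, the distance of each hypomorph from the midpoint of control and null. Errors of a log2 change are standard errors from limma, and group levels are mean ± SD of the signal. Tables were prepared with python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

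Gene lists were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 20 lists in each comparison. They covered sarcomere proteins; muscle membrane, calcium and energy genes; myoblast fusion; muscle attachment and integrin adhesion; founder identity factors; early mesoderm and myogenic regulators; visceral muscle; heart; fat body; hemocytes; neurons and neuroblasts. The others were glia, epidermis and cuticle, trachea, gut endoderm, cell cycle, apoptosis, ecdysone response, heat shock and ribosomal proteins. Camera with a correlation estimated for each list, and fry, which tests whether a list's genes move on balance one way, were alternatives. The camera calls that held with an estimated correlation were the sarcomere list in the null, 113 and 424, and the visceral muscle list in the null. The genotype groups, contrasts, thresholds, lists and the rule for named genes were fixed before the data were examined.

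The genes named in the text were, with the pseudocount of 16, the 12 largest falls and 8 largest rises per allele among called genes whose 4 mutant arrays all lay on one side of all 4 control arrays. To these were added the 5 largest each way per step by the same rule, the 4 largest each way per midpoint contrast, and up to 4 members per list with the smallest p in the null. Other list members are named as examples chosen after their values were seen.

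The procedure was tested on simulated data over the same 8357 genes. For the null contrast, 55.2% of genes changed by 0.5 on the log2 scale, 83.6% of those changed by 1 and 100% of those changed by 2 were recovered, and 7.02% of calls were false. For 65 against control the shares were 34.3%, 83.6% and 100%, with 2.03% false calls. The number of arrays limits the precision throughout.

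The alternatives were a pseudocount of 1 or 64, quantile normalisation, median centring, no filter or a filter on the lowest 50%, the mean of a gene's probe sets or all probe sets separately, only the groups compared in the fit, eBayes without the trend, array weights, the replicate number or the hybridisation day as a block, an adjusted p under 0.01, and each array left out in turn. Choosing the fluidics module as a block, and leaving out the 5 arrays numbered 4, came after seeing the data. All 4 control arrays were run on 1 fluidics module that held 2 null arrays and no hypomorph array, so the module and the contrast of a hypomorph with the control are linked only through the null arrays. Control, 424, 113 and null had 1 array on each of the 4 hybridisation days, so a shift common to a day cancels between them. The day as a block therefore cannot move these changes and alters only their errors, so it is no further test of them. Counts of called genes with the same sign within days or modules use the arrays that gave the calls. High agreement there is largely built in and tests nothing further.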

Results

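Whole embryos at mid stage 13, early in muscle differentiation, were profiled in 5 genotypes that differ in the activity of mef2, with 4 arrays per genotype. The question the design poses is how the level of Mef2 activity affects which genes are expressed, from the control through the hypomorphic alleles 65, 424 and 113 to the null. Median signals per array lay between 33.7 and 37.4, with 33.7 to 34.8 in the null and 35.5 to 37.3 in the control. Arrays of 1 genotype correlated with each other at a Pearson r of 0.964 to 0.977 across genes, which are not independent replicates, and the median SD within a genotype was 0.183 to 0.200 on the log2 scale. The first principal component of the 8357 genes held 19.8% of the variance and set the null arrays, at 23.9 to 26.3, apart from the rest, at -9.55 to -1.43. The second held 11.9% and set the control arrays apart, at -19.8 to -15.7. Mef2 had no named probe set, so its own level was not analysed here.

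**Figure D1:**
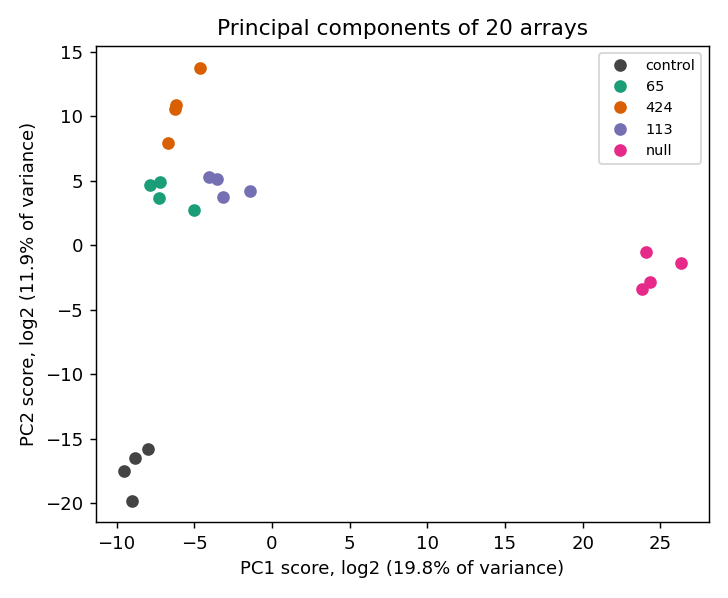
Scores of the 20 arrays on the first (19.8% of variance) and second (11.9%) principal components of log2(signal + 16), coloured by genotype. The 4 null arrays lie at 23.9 to 26.3 on the first component, and the 4 control arrays at -19.8 to -15.7 on the second.

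In the null, most measured genes of the contractile apparatus fell. Mlc2, the regulatory light chain of muscle myosin, went from a signal of 514 ± 49.9 in the control to 46.3 ± 7.33 in the null (mean ± SD, n = 4 each), a log2 change of -3.09 ± 0.13 (SE). Mlc1, the alkali light chain, changed by -3.09 ± 0.19, and TpnC73F, a calcium-binding troponin C, by -2.94 ± 0.18. The troponin T gene up changed by -2.54, Msp300, a giant nesprin, by -2.41, the tropomyosin gene Tm2 by -2.29, the titin-related gene sls by -1.78 and bt, which encodes projectin, by -1.49. The null signals of Mlc1, TpnC73F, up, sls and bt lay under the filter level of 9.29, so the sizes of these changes depend on the pseudocount. With 1 and 64 they were -4.99 and -1.68 for Mlc1, -5.23 and -1.55 for TpnC73F, and -4.16 and -1.34 for up. Of the 17 measured members of the sarcomere list, 12 fell, 1 rose and 4 were not called over all genes. Adjusted over the list alone, 13 fell and 1 rose. The member that rose was tmod, which encodes the pointed-end cap tropomodulin, at 0.28. Camera gave an adjusted p of 2.00e-13 for the list, and adjusted p = 7.92e-05 with an estimated correlation. The median log2 change of the members was -0.75, -0.82, -0.84 and -0.74 within the 4 hybridisation days, and camera gave an adjusted p of 1.62e-12 with the day as a block.

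**Figure D2:**
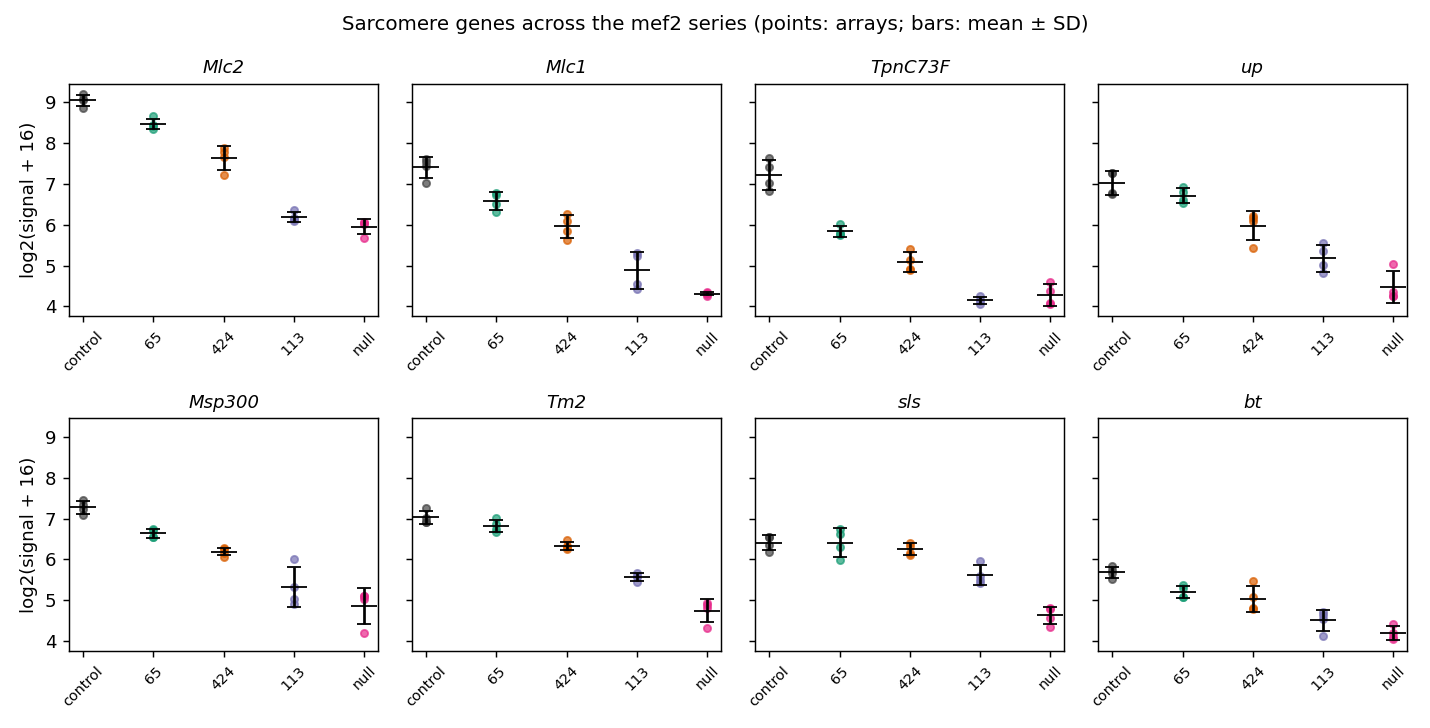
Signals of the 8 sarcomere list members with the largest falls in the null, as log2(signal + 16) on the vertical axis, in control, 65, 424, 113 and null embryos. Points are arrays and bars are the mean ± SD of 4 arrays; Mlc2 changed by -3.09 and sls by -1.78 on the log2 scale between control and null.

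Visceral muscle was the other list called in the null. Of its 8 members 5 fell and none rose over all genes, with the same 5 adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.0482 with an estimated correlation). HLH54F, a regulator of the caudal visceral mesoderm, changed by -1.28, the homeobox gene bap by -0.64, betaTub60D, a tubulin of differentiating mesoderm, by -0.49 and the forkhead gene bin by -0.43. The members' median was -0.28, -0.36, -0.38 and -0.56 within the 4 days, and the camera adjusted p was 0.0136 with the day as a block. The call of bin was lost after median centring (limma adjusted p = 0.0519) and quantile normalisation (limma adjusted p = 0.0608), and without any 1 of null replicates 1, 2 and 3 or control replicates 3 and 4, at -0.43 to -0.33. Among muscle membrane, calcium and energy genes, 7 of 21 members fell and 1 rose (7 and 1 adjusted over the list alone), and camera did not call the list at an adjusted p of 0.0861. Argk1, the arginine kinase that buffers muscle ATP, changed by -1.74, GluRIIB, a glutamate receptor subunit of the neuromuscular junction, by -1.08 to a signal under the filter level, the sarcoglycan gene Scgalpha by -1.04 and the L-type calcium channel gene Ca-alpha1D by -0.89.

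Myoblast fusion genes moved in both directions. In the null, sing, which encodes a membrane protein needed for fusion, changed by -2.53 and the scaffold gene rols by -0.51, while the verprolin gene Vrp1 rose by 0.72, the Hedgehog co-receptor gene ihog by 0.66 and the fusion-competent myoblast factor lmd by 0.42. This made 3 higher and 2 lower of 15, also adjusted over the list alone, with a camera adjusted p of 0.806; the members' median was 0.12 and their mean -0.04. With the mean of its probe sets, rols was at -0.24 and was not called (limma adjusted p = 0.317). In muscle attachment and integrin adhesion, 7 of 25 fell and 4 rose (10 and 5 adjusted over the list alone; camera adjusted p = 0.472). The integrin ligand gene Tig changed by -1.11, if, the alpha-PS2 integrin, by -0.95, parvin by -0.70, stck, the PINCH adaptor, by -0.48 and mys, the beta-PS integrin, by -0.41, whereas rhea, the talin gene, rose by 0.40.

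Regulators of the mesoderm also split. Of 23 early mesoderm and myogenic regulators in the null, 7 fell and 3 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.472). The zinc-finger gene zfh1 changed by -1.19 and nau, the fly MyoD homologue, by -0.76. Founder identity factors gave 5 lower and 3 higher of 24 (5 and 4 over the list alone; camera adjusted p = 0.806), with caup, an Iroquois gene, up by 0.68 and the muscle identity gene Dr down, at -0.50. The heart list had 1 member higher of 18 (camera adjusted p = 0.907), mid at 0.40, which was at 0.33 and not called without null replicate 4.

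Camera called no list for other tissues in the null. The alternative fry called trachea (fry adjusted p = 0.000216), glia (fry adjusted p = 0.00794) and epidermis (fry adjusted p = 0.0390), each pointing down. Glia had 4 lower and 2 higher of 10 (camera adjusted p = 0.617), with a median of -0.21 over the members. Against that direction, repo, the glial homeobox regulator, rose by 0.91 and nrv2, a sodium pump subunit, by 0.78. Among the members that fell was htl, at -0.49. Epidermis and cuticle had 5 lower and 2 higher of 24 (adjusted p = 0.803), including a change of -2.24 in pio, which encodes an apical matrix protein, and a rise of 1.00 in the epidermal factor grh. Trachea had 1 higher and 1 lower of 10 (adjusted p = 0.803; median 0.01, mean -0.19) and fat body 1 lower of 5 (adjusted p = 0.567), the lipoprotein gene apolpp at -0.48. Hemocytes had 1 higher of 15 (adjusted p = 0.567), the collagen gene Col4a1 at 0.37. Neurons and neuroblasts had 1 lower of 16 (adjusted p = 0.993), dpn at -0.38. Without null replicate 4, Col4a1 was at 0.31 and dpn at -0.27, and neither was called. Gut endoderm had 0 called of 12 (camera adjusted p = 0.806; median -0.01, mean 0.04). Adjusted over the list alone, glia had 5 lower and 2 higher, epidermis 6 lower and 2 higher, and the counts of the heart and of the other lists for these tissues were as over all genes.

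Camera called no list for general cell states in the null either, and fry called only the cell cycle, pointing up (fry adjusted p = 0.0422). The cell cycle list had 2 higher and 1 lower of 17 (4 and 1 over the list alone; camera adjusted p = 0.414), with the replication genes Mcm5 at 0.50 and PCNA at 0.42. The lower member was Cdk2 at -0.26, whose call was lost in 25 alternatives. Apoptosis had 2 lower of 9 (adjusted p = 0.806), Diap2 and Dark, which were at -0.39 and -0.32 and not called with the module as a block. The ecdysone response had 1 higher and 2 lower of 17 (adjusted p = 0.806), among them usp, the partner of the ecdysone receptor, which fell from a signal of 124 ± 23.9 to 45.2 ± 12.3 (n = 4 each). Heat shock had 1 higher and 1 lower of 7 (adjusted p = 0.806), Hsc70-4 at 0.36 and the small heat shock gene Hsp27 at -1.05. The call of Hsp27 was lost in 11 alternatives, among them those without null replicate 3 or 4 or control replicate 1, 2 or 4, at -1.05 to -0.79. Ribosomal proteins had 0 called of 8 (camera adjusted p = 0.803). Adjusted over the list alone, the counts of the lists after the cell cycle were as over all genes.

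Large changes in the null also lay outside these lists. In each gene named here for the size of its change against the control, all 4 mutant arrays lay beyond all 4 control arrays. Uhg1, a host gene of small nucleolar RNAs, went from 318 ± 28.9 to 3.29 ± 3.39 (n = 4 each), a log2 change of -4.13 that was -6.47 with a pseudocount of 1 and -2.50 with 64 (limma with Benjamini-Hochberg adjustment, adjusted p = 2.91e-17). CG6972 changed by -3.60, MFS18 by -3.52, CG34247 by -2.75, the adenylyl cyclase gene ACXD by -2.68, CG5080 by -2.59 and sprt by -2.52. RanBPM, a scaffold protein, rose from 36.6 to 389 ± 28.2 (log2 2.95 ± 0.14, 7.73-fold, limma adjusted p = 1.19e-13). CG2233 rose by 2.60, the serine protease gene teq by 2.55, the tetraspanin gene Tsp42Ek by 2.29, CG42807 by 2.05, CG7742 by 2.03, CG13427 by 1.97 and Nop60B, a pseudouridine synthase of small nucleolar particles, by 1.92. The other 3 probe sets of teq did not share its sign. The null signals of CG6972 and ACXD and the control signal of Nop60B lay under the filter level, so the sizes of their changes depend on the pseudocount too. In total limma called 1657 of 8357 genes between null and control, 741 higher and 916 lower, of which 62 rose and 145 fell at least 2-fold on this scale. After median centring of the arrays the split was 970 higher and 746 lower. The day as a block gave 1824 called genes, and 1567 of the 1657 had the same sign on all 4 days. The same arrays gave the calls, so this agreement, here and in the other comparisons, is largely built in. Genes of the second chromosome, where mef2 lies, made up 42.6% of the changed genes and 38% of all tested genes (Fisher's exact odds ratio 1.28, 95% interval 1.14 to 1.43).

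**Figure D3:**
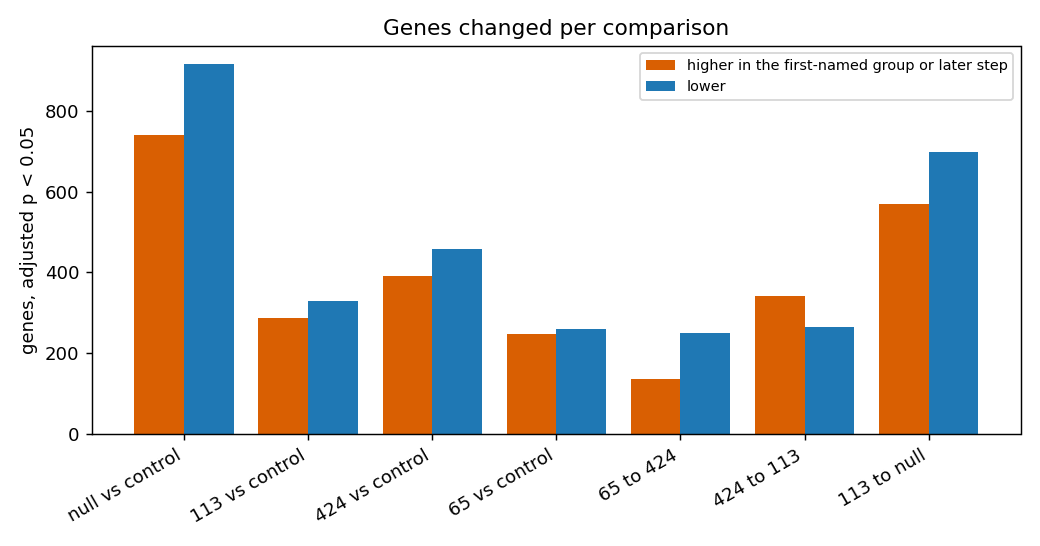
Number of genes higher (up) and lower (down) at an adjusted p under 0.05 in each comparison, vertical axis from 0. The null had 741 higher and 916 lower genes against the control, and 65 had 248 and 259.

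In 113, the strongest of the hypomorphic alleles, the sarcomere genes were again the list with the lowest p. TpnC73F changed by -3.07, Mlc2 by -2.85, Mlc1 by -2.52, Msp300 by -1.96, up by -1.84, Tm2 by -1.45, bt by -1.18 and sls by -0.79, and tmod rose by 0.29. The signals of TpnC73F and bt in 113 lay under the filter level, and TpnC73F was at -5.68 and -1.59 with a pseudocount of 1 and 64. This was 8 lower and 1 higher of 17, also adjusted over the list alone (camera adjusted p = 3.44e-10, and adjusted p = 0.000390 with an estimated correlation). The members' median was -0.49, -0.43, -0.30 and -0.54 within the 4 days, and camera gave an adjusted p of 3.10e-09 with the day as a block. Visceral muscle was called at a camera adjusted p of 0.0240, with 2 of 8 members lower (3 over the list alone), HLH54F at -0.62 and bin at -0.55. That call was lost at adjusted p = 0.0673 with an estimated correlation. Its median was -0.20, -0.29, -0.44 and -0.13 within the 4 days, and its camera adjusted p was 0.0275 with the day as a block and 0.229 with the fluidics module as a block. Without replicate 4 of 113, or without replicate 2 of the control, 1 list was called in place of 2.

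The other muscle lists were not called in 113. Of the muscle membrane, calcium and energy genes 4 of 21 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.227), among them Ca-alpha1D at -0.79 and Argk1 at -0.78. Muscle attachment and integrin adhesion had 3 lower and 1 higher of 25 (5 and 2 over the list alone; camera adjusted p = 0.227), with mys at -1.42. Myoblast fusion had 2 higher and 1 lower of 15 (5 and 1 over the list alone; camera adjusted p = 0.543), with Vrp1 at 0.70 and sing at -0.76. The MyoD homologue nau fell by 0.56. Of 23 early mesoderm and myogenic regulators 4 fell and 1 rose (6 and 1 over the list alone; camera adjusted p = 0.122). The ecdysone list had a median of 0.01 and a mean of -0.05, and camera pointed down without a call.

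Outside the lists, Drsl5, a gene of the drosomycin family of antimicrobial peptides, rose in 113 from 7.63 to 1462 ± 115 (n = 4; limma, Benjamini-Hochberg adjusted p = 1.43e-17). The control signal of Drsl5 lay under the filter level of 9.29, so the size of the rise depends on the pseudocount. The same held for CG3734, which rose from 6.28 to 148, by 4.47 and 1.59 on the log2 scale with a pseudocount of 1 and 64. The neprilysin gene Nep2 rose by 1.83, mwh, which shapes wing hairs, by 1.77, the T-box gene bi by 1.53 and Anp, the antibacterial peptide andropin, by 1.52. CG6972 changed by -3.68, CG34247 by -2.95, udd, a factor for ribosomal RNA transcription, by -2.60 and Smyd4-2, a SET and MYND domain gene, by -2.57. CG3552 changed by -2.40, ACXD by -2.38, CG5039 by -2.33, the DNase gene Sid by -2.18 and Prosbeta2R2, a proteasome subunit gene, by -2.10. The signals of CG6972, Smyd4-2 and Prosbeta2R2 in 113 lay under the filter level, so the sizes of their falls have the same limit. The RNA-binding protein gene larp rose by 1.31 on its brightest probe set, and its other probe set had the opposite sign. limma called 617 genes, 287 higher and 330 lower. The count was 712 with the day as a block, and 607 of the 617 genes had the same sign on all 4 days. With the fluidics module as a block it was 82, at a standard error 1.83-fold as large, and 616 of the 617 kept their sign. The calls of bi and Anp were lost there at log2 changes of 1.57 and 1.48, close to those without the block. Of the changed genes 20.3% lay on the second chromosome, against 38% of those tested (odds ratio 0.392, 95% interval 0.318 to 0.481).

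In 424, of intermediate activity, most of the sarcomere genes lower in 113 were lower as well. TpnC73F changed by -2.14, Mlc1 by -1.44, Mlc2 by -1.41, Msp300 by -1.08, up by -1.05, Tm2 by -0.69, bt by -0.64 and Actn, the alpha-actinin gene, by -0.45, while sls was at -0.16 and was not called. The list had 8 lower and 1 higher of 17 (8 and 2 adjusted over the list alone), with a camera adjusted p of 0.000548 and adjusted p = 0.0339 with an estimated correlation. The member that rose was tmod, by 0.52. Within the 4 days the median was -0.34, -0.59, -0.18 and -0.39, and with the day as a block camera gave an adjusted p of 0.000784. Argk1 changed by -0.95 and the integrin gene mys by -1.41.

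A further 3 lists were called in 424. The ecdysone response (camera adjusted p = 0.0397, lost at adjusted p = 0.249 with an estimated correlation) had 3 of 17 members lower and 1 higher, also over the list alone. The largest of these was ImpE2, an ecdysone-inducible gene of imaginal discs, whose signal was 728 in the control, 51.9 in 424 and 834 in 113. It fell by 3.48, 11.2-fold (limma adjusted p = 2.11e-13), ImpL1 changed by -0.63 and usp by -0.85, and the insulin-binding protein gene ImpL2 rose by 0.40. Heat shock (adjusted p = 0.0397, lost at adjusted p = 0.357 with an estimated correlation) had 1 of 7 members lower, the co-chaperone gene DnaJ-1 at 898 ± 408 against 1932 ± 291 in the control (n = 4 each), and 2 over the list alone, with a median of -0.67 over the members. Epidermis and cuticle (adjusted p = 0.0409, lost at adjusted p = 0.357 with an estimated correlation) had 4 of 24 members lower, and 4 lower and 1 higher over the list alone. Those were Nrx-IV, a septate junction gene, at -1.22, sha at -0.95, the bundling protein gene f at -0.52 and the chitin-binding protein gene obst-A at -0.45. Within the 4 days the median was -0.04, -0.18, -0.19 and -0.22 for the ecdysone response, 0.07, -0.75, -0.68 and -1.04 for heat shock, where day 1 lay above 0, and -0.10, -0.15, -0.09 and -0.18 for epidermis. The camera adjusted p with the day as a block was 0.0404 for the ecdysone response, 0.0404 for epidermis and 0.0455 for heat shock, and with the module as a block it was 0.0225, 0.244 and 0.516 in the same order. Without replicate 2 or 4 of 424, or replicate 2 of the control, 1 list was called in place of 4. The founder factors had a median and a mean of -0.02 with camera pointing up, and fat body a median of 0.09 with a mean below 0.

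Drsl5 rose in 424 as well, to 1007 ± 126 (n = 4), at a log2 change of 7.19 and 3.90 with a pseudocount of 1 and 64. CG3690 rose by 3.21, CG6293 by 1.85, larp by 1.59, CG13023 by 1.49, pigs by 1.45, the glutathione transferase gene GstD5 by 1.37 and CG17111 by 1.36. Among the falls, Sid changed by -3.31, zfh1 by -2.37 (limma adjusted p = 2.13e-12), the intraflagellar transport gene Oseg2 by -2.31, the microtubule-binding protein gene Map205 by -2.29, the cuticle gene TwdlN by -2.07 and the globin gene glob1 by -2.05. CG34247, CG3552, ACXD and CG6972 changed by -2.70, -2.63, -2.57 and -2.40. Signals lay under the filter level in 424 for Sid, TwdlN and ACXD and in the control for pigs and CG17111, so the sizes of their changes depend on the pseudocount, and Sid was at -5.76 and -1.78 with 1 and 64. limma called 849 genes, 390 higher and 459 lower, and 972 with the day as a block. Of the 849, 821 had the same sign on all 4 days. The module as a block left 80 called genes, at a standard error 2-fold as large, and 845 of the 849 kept their sign. The calls of CG6293, CG13023 and CG17111 were lost there at log2 changes of 1.69, 1.43 and 1.45, and that of pigs at 0.95. The second chromosome held 27% of the changed genes (odds ratio 0.574, 95% interval 0.488 to 0.674).

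In 65, the mildest allele, few sarcomere genes were called. TpnC73F changed by -1.38, Mlc1 by -0.82 and Mlc2 by -0.58, from 514 ± 49.9 to 340 ± 32.6 (n = 4 each), and tmod rose by 0.38. Msp300 at -0.64, up at -0.31, Tm2 at -0.21 and sls at 0.01 were not called. That made 3 lower and 1 higher of 17 (4 and 1 adjusted over the list alone), and camera did not call the list at an adjusted p of 0.160. The members' median was -0.07 and -0.09 on the 2 days that held 65 and control arrays, and the camera adjusted p was 0.159 with the day as a block. The signal of GluRIIB fell from 33.9 ± 9.95 to 8.88 ± 4.56 (n = 4 each), mys changed by -1.10 and usp by -0.58.

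Camera called 0 of the 20 lists in 65. The sarcomere, fusion, heart and heat shock lists had an unadjusted camera p under 0.05, and fry called 3 lists. Of the heat shock list, Hsp27 changed by -1.15 and DnaJ-1 by -0.98 (2 of 7, camera adjusted p = 0.0917). Without replicate 4 of 65, 2 lists were called, and without replicate 1 of 424 or replicate 3 of the control, 1. The median, mean and camera direction did not share a sign for the founder, visceral muscle, fat body, hemocyte, glia and ecdysone lists in 65, with medians between -0.01 and 0.04.

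Drsl5 rose to 1640 ± 312 in 65 (n = 4; limma, Benjamini-Hochberg adjusted p = 8.09e-18), at a log2 change of 6.15, or 7.88 and 4.56 with a pseudocount of 1 and 64. Tep4, a thioester protein related to complement, went from 603 to 69.8, 7.14-fold lower at a log2 change of -2.84, and stood at 513 in 424 and 566 in 113. ACXD changed by -2.56, CG3552 by -2.46, CG34247 and CG5039 by -2.43 each, Oseg2 by -2.24, Sid by -2.09, CG8607 by -2.06, udd by -2.01, Prosbeta2R2 by -1.89, CG7484 by -1.78 and CG7912 by -1.76. Nep2 rose by 1.64, thw by 1.59, larp by 1.55, CG42324 by 1.41, GstD5 by 1.36, mwh by 1.27 and CG15098 by 1.25. Signals of CG8607 and CG7912 in 65 and of thw in the control lay under the filter level, and CG8607 was at -3.88 and -0.95 with a pseudocount of 1 and 64. limma called 507 genes, 248 higher and 259 lower, and 548 with the day as a block. Of the 507, 506 had the same sign on both days with 65 and control arrays. The module as a block left 64, and 506 of the 507 kept their sign. The call of CG15098 was lost there at a log2 change of 1.12. The second chromosome held 15.6% of the changed genes (odds ratio 0.285, 95% interval 0.221 to 0.365).

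**Figure D4:**
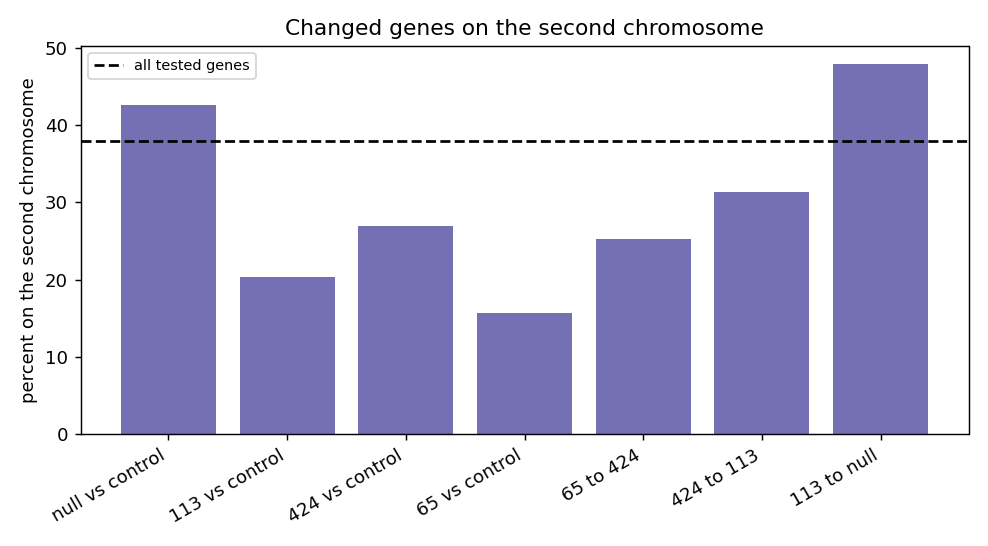
Percent of the changed genes that lie on the second chromosome in each comparison, with a dashed line at the 38% of all tested genes. The share was 42.6% in the null, 20.3% in 113, 27% in 424 and 15.6% in 65 against the control.

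The steps between adjacent alleles tested where along the series each gene moved. From 65 to 424, Mlc2 changed by -0.84, TpnC73F by -0.75, up by -0.74 and Tm2 by -0.48, 4 of the 5 sarcomere members lower at this step. Lists were counted by member at the steps and not tested with camera. ImpE2 changed by -3.62, CG10591 by -1.73, Meics by -1.70, the cuticle gene Cpr11A by -1.63 and slf by -1.62, and 5 of 24 epidermal genes fell with none higher. Tep4 rose by 2.61, udd by 2.47, CG3690 by 2.30, CG5039 by 1.91 and the glutathione transferase gene GstE3 by 1.78. Cell cycle genes had 3 of 17 members higher and 0 lower. limma called 385 genes, 136 higher and 249 lower, and 371 with the day as a block. Of the 385, 384 had the same sign on both shared days and all 385 on the shared module. These signs also come from the arrays that gave the calls, so they test neither day nor module. With the module as a block 214 were called, and the second chromosome held 25.2% of the 385.

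From 424 to 113, 7 of 17 sarcomere members fell and 0 rose. Mlc2 changed by -1.43, Mlc1 by -1.08, TpnC73F by -0.94, Msp300 by -0.87, up by -0.79, Tm2 by -0.76 and sls by -0.63. Of the epidermal genes 6 of 24 rose and 0 fell, and ImpE2 rose by 3.65. CG3734 rose by 2.80, Anp by 1.98, CG10591 by 1.91 and htt, the huntingtin homologue, by 1.82, while udd changed by -3.06, CG3690 by -2.28, CG6293 by -1.84, CG5039 by -1.81 and the double-stranded RNA-binding protein gene blanks by -1.58. Signals of CG3734, Anp and htt in 424 and of TpnC73F in 113 lay under the filter level, and CG3734 was at 4.32 and 1.56 with a pseudocount of 1 and 64. limma called 606 genes, 342 higher and 264 lower, and 726 with the day as a block. Of the 606, 596 had the same sign on all shared days and all 606 on the shared module. With the module as a block 311 were called, and the second chromosome held 31.4% of the 606.

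From 113 to the null, sls changed by -0.99, Tm2 by -0.83, up by -0.70 and Mlc1 by -0.57, among 8 of 17 sarcomere members lower and 0 higher. Mlc2 at -0.24 (limma adjusted p = 0.215) and TpnC73F at 0.13 (limma adjusted p = 0.709) were not called at this step. The signal of TpnC73F lay under the filter level of 9.29 in both genotypes, at 1.75 ± 1.01 and 3.65 ± 3.66 (n = 4 each), so a further fall could not have shown. Fusion genes had 4 of 15 lower and 1 higher, and epidermal genes 6 of 24 lower and 1 higher. Drsl5 changed by -5.99, Uhg1 by -4.03, MFS18 by -3.61, CG3734 by -2.93 and the odorant-binding protein gene Obp44a by -2.91. RanBPM rose by 3.11, CG13427 by 2.09, Nop60B by 2.08, Tsp42Ek by 1.98 and the cytochrome P450 gene Cyp28d1 by 1.90. Signals of Drsl5, Uhg1, CG3734, Mlc1, up and sls in the null and of Nop60B in 113 lay under the filter level, so the sizes of these changes depend on the pseudocount, and Drsl5 was at -7.72 and -4.41 with 1 and 64. limma called 1268 genes, 569 higher and 699 lower, and 722 higher and 559 lower after median centring. With the day as a block 1410 were called, and 1206 of the 1268 had the same sign on all shared days and all 1268 on the shared module. With the module as a block 576 were called. The second chromosome held 47.9% of the 1268 (odds ratio 1.62, 95% interval 1.44 to 1.84).

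Over the activity rank as a whole, several genes of the contractile apparatus rose with activity, but not every sarcomere member was graded. Mlc2 rose with activity by 0.85 per step (limma adjusted p = 1.11e-12), Mlc1 by 0.79, TpnC73F by 0.76, up by 0.66, Msp300 by 0.61, sing by 0.59, Tm2 by 0.58, sls by 0.44, Argk1 by 0.40 and bt by 0.37 on the log2 scale. Among members called lower in the null, Act87E had log2 signals of 11.14 to 11.32 in the control and 10.92 to 11.06 in the null. In 424 it was at 11.40 to 11.44, above the control. Actn was at 7.92 to 8.44 in 424 and at 8.36 to 8.57 in 113. The receptor gene usp rose by 0.28 per step. The glial regulator repo changed by -0.16 per step with activity and the epidermal factor grh by -0.18. The slope of tmod, at -0.05 (limma adjusted p = 0.337), was not called, and Uhg1, which was low only in the null by its mean signals, had a slope of 0.87. The slopes of Mlc1, TpnC73F, up, sls, bt and Uhg1, under the filter level at the null end, depend on the pseudocount. limma called 872 genes, of which 520 rose and 352 fell with activity, and 417 rose and 487 fell after median centring. Without null replicate 4 the count was 554 and without null replicate 3 it was 570. It was 796 with the day as a block.

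The midpoint contrast asked whether a gene that fell in the null stood nearer to the control or to the null in each hypomorph. The answer varied among the sarcomere genes. Mlc2 lay nearer to the null in 113 at -1.30 on the log2 scale (limma adjusted p = 1.12e-09), was at 0.13 in 424 (limma adjusted p = 0.339) and lay nearer to the control in 65 at 0.97 (limma adjusted p = 1.91e-07). TpnC73F lay nearer to the null in 113, at -3.07 and -0.82 with a pseudocount of 1 and 64. Its null signal of 3.65 lay under the filter level, as did that of sls at 8.96, so the position of their midpoints depends on the pseudocount. Tm2 was nearer to the control in 424 at 0.45 and nearer to the null in 113 at -0.31 (limma adjusted p = 0.0438), and sls was nearer to the control in 424 at 0.73 and undecided in 113 at 0.10 (limma adjusted p = 0.626). The fusion gene sing was nearer to the control in all 3 hypomorphs, at 1.39 in 65, 1.26 in 424 and 0.50 in 113.

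Among the genes with the largest midpoint values at the pseudocount of 16, Uhg1 and MFS18 were nearer to the control in every hypomorph, Uhg1 at 1.96 and MFS18 at 1.85 in 113. Obp44a at 1.65 and the actin nucleation gene Arpc2 at 1.49 followed in 113, GstD5 at 1.64 and udd at 1.58 in 424, and Obp44a at 1.69 and GstD5 at 1.62 in 65. Nearer to the null were CG6972 at -1.88 and CG5039 at -1.67 in 113, Sid at -2.19, zfh1 at -1.77, Map205 at -1.67 and TwdlN at -1.57 in 424, and CG5039 at -1.76, CG7484 at -1.58, CG3552 at -1.37 and CG7912 at -1.31 in 65. Signals of Uhg1 in the null, CG6972 in 113 and the null, Sid and TwdlN in 424 and CG7912 in 65 lay under the filter level, and with a pseudocount of 1 and 64 Uhg1 was at 3.13 and 1.17 in 113. Of the 916 genes lower in the null, limma placed 324 in 113 (235 nearer to the control and 89 nearer to the null), 397 in 424 (302 and 95) and 400 in 65 (330 and 70). The levels of control and null come from the arrays that selected the 916 genes, which widens the distance between them. With the day as a block 361, 435 and 395 were placed, and with the module as a block 111, 120 and 136.

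Several genes changed alike in all 4 mutants. GluRIIB, mys, zfh1, usp and the integrin ligand gene Tig fell in each, and lmd, caup, rhea and tmod rose in each. In total 86 genes were lower and 78 higher in all 4 alleles against the control, 164 together. Simulations of all 20 arrays with no change in any group gave 0 in 50 draws. Such data yield few calls at all, so that 0 does not show what shared controls add. Each pair of alleles shared more calls than independent lists would. Null and 113 shared 211 lower genes where independent lists give 36.2, and a median of 115 when each was set against a different pair of control arrays. For 113 and 65 the values were 152, 10.2 and 70.5. The covariance of the log2 changes across genes was 0.0537 to 0.0662 over the 6 pairs of alleles, against 0.0170 to 0.0171 in simulation. The correlation across genes, which are not independent replicates, was 0.461 for null and 424 and 0.459 for null and 65, each below its simulated value (0.499 for null and 65), and 0.524 to 0.703 for the other pairs. The 164 genes held 12.2% second-chromosome genes (odds ratio 0.222, 95% interval 0.131 to 0.357). A further 550 genes were called lower and 471 higher in the null and were not called in either direction in any other allele, a description of calls and not a test of the difference.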

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

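The comparison of each array with the others of its genotype was planned, and no test here was chosen after its result was seen. In each group of 4 arrays, the array farthest out was compared with its nearest neighbour, and the gap was divided by the range of the group. This picks out about 1 in 20 groups by chance.

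Among the means of gene lists and principal components, 3 of 110 groups had an array apart. Hemocyte genes had a mean log2 signal of 7.619 in null replicate 2, against 7.678 to 7.688 in the other null arrays. Glial genes stood at 7.524 in 113 replicate 2, against 7.431 to 7.443. Epidermal and cuticle genes stood at 7.337 in replicate 4 of 65, against 7.558 to 7.59, and the run record of that array says that a protocol was aborted.

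Among the 135 genes that the naming rule selected, which include up to 4 members of each list, 49 of 675 groups had an array apart. The arrays most often apart were control replicate 1, with 7 genes, 424 replicate 4, with 6, null replicate 4, with 5, and control replicate 4, with 4. The share of the range taken by the gap was as follows for muscle and mesoderm genes. It was 0.91 for Mlc2 and 0.883 for up in null replicates 1 and 4, 0.832 for TpnC73F in 65 replicate 2, 0.926 for the integrin gene if in 113 replicate 4, 0.852 for caup and 0.858 for robo1 in 424 replicate 4, and 0.854 for pdm3 in 424 replicate 1. For the heart genes mid and svp it was 0.834 in control replicate 1 and 0.882 in 65 replicate 4.

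For genes of blood, fat body and the nervous system, the share was 0.839 and 0.942 for apolpp in 424 replicate 4 and null replicate 4, 0.918 for the GATA factor gene srp in control replicate 1, and 0.957 for the phenoloxidase gene PPO3 in null replicate 4. It was 0.866 for dpn in null replicate 4, 0.923 for fne in 113 replicate 4 and 0.865 for nrv2 in 424 replicate 3. Among epidermal, tracheal and gut genes it was 0.831 for pio in null replicate 3, 0.956 for verm in control replicate 4, 0.835 and 0.854 for Nrx-IV in control replicate 2 and 65 replicate 4, 0.973 for kni in control replicate 4 and 0.941 for Ptx1 in control replicate 1. In the general lists it was 0.869 for Cdk2 in null replicate 2, 0.991 for the caspase gene Dcp-1 in null replicate 1, 0.895 for usp in control replicate 4, 0.875 for ImpL2 in null replicate 2, 0.861 for E23 in 65 replicate 3 and 0.854 for RpL3 in 424 replicate 1.

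Genes named for the size of their change gave the remaining values. Control replicate 1 was apart for CG5080 (0.841), bi (0.896), Tep4 (0.947) and CG8607 (0.884), control replicate 3 for CG2233 (0.833) and htt (0.893), and control replicate 4 for mwh (0.891). Among the 65 arrays, replicate 1 was apart for CG5080 (0.851) and udd (0.846), replicate 2 for teq (0.841), replicate 3 for Nop60B (0.907) and replicate 4 for Nep2 (0.845). In 424, replicate 4 was apart for CG34247 (0.845), Oseg2 (0.871) and CG6293 (0.955), and replicate 2 for TwdlN (0.952). The share was 0.842 for Prosbeta2R2 in 113 replicate 4. In the null, it was 0.954 for Uhg1 in replicate 2, 0.834 for Nop60B and 0.897 for udd in replicate 3, and 0.973 for Arpc2 in replicate 4.

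Probe sets without a single gene symbol, which have several symbols or none, also responded. Of the 1112 such probe sets that passed the filter, limma called 184 in the null, 75 in 113, 98 in 424 and 67 in 65 against the control. Their genes are not named here.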

How the results depend on the processing

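The fluidics module as a block and the fit without the 5 arrays numbered 4 were chosen after seeing the data, and all other alternatives were planned. No count of genes moved by more than 1.5 times under another pseudocount, normalisation, centring, filter, choice of probe sets, variance model, array weighting or set of groups in the fit. Under these and the day and replicate blocks the counts ran from 1409 to 1883 for the null, 548 to 733 for 113, 742 to 1037 for 424 and 401 to 599 for 65. An adjusted p under 0.01 lowered them to 995 for the null, 345 for 113, 445 for 424, 289 for 65, 214, 302 and 739 for the steps down the series, 361 for the trend, and 187, 238 and 226 for the midpoint of 113, 424 and 65. The module as a block left 82 for 113, 80 for 424, 64 for 65, 214, 311 and 576 for the steps, and 111, 120 and 136 for the midpoint. Standard errors of the hypomorph contrasts and steps rose by 1.15-fold to 2-fold there, as groups share few modules. Some changes moved too, in 424 pigs from 1.45 to 0.95 and CG17111 from 1.36 to 1.45. An effect of the module itself on these counts cannot be told apart. The null count with the module as a block was 1106 and the trend 1071. Without the arrays numbered 4 the trend count was 490; fewer arrays entered that fit.

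Counts of called lists were less stable. With no filter 1 list was called in 113, and with the dimmest 50% left out 1 in 424. An estimated correlation left 1 each in 113 and 424, and fry called 9 in the null, 6 in 113, 10 in 424 and 3 in 65. Those in the null were sarcomere, visceral muscle, muscle membrane, muscle attachment, early mesoderm, glia, epidermis, trachea and cell cycle. Of these only the cell cycle pointed up. The module block left 1 in 113 and 2 in 424. Without the arrays numbered 4, 2 were called in 424 and 2 in 65. The cause of these moves was not tested.

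With each array left out in turn, the counts ran from 1408 to 1687 for the null, 470 to 642 for 113, 632 to 865 for 424, 378 to 528 for 65, 290 to 400, 434 to 640 and 1018 to 1282 for the steps. The trend ran from 554, without null replicate 4, to 949, and was 570 without null replicate 3. Lists ran from 2 to 3 in the null, 1 to 3 in 113, 1 to 5 in 424 and 0 to 2 in 65. The lowest counts came without 113 replicate 4 or control replicate 2 in 113, and without 424 replicates 2 or 4 or control replicate 2 in 424. In 65, 2 lists were called without 65 replicate 4 and 1 without 424 replicate 1 or control replicate 3.

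Over 207 results for named genes, 7279 of 7397 comparisons with an alternative kept direction and side of the threshold, 76 lost the call, 42 gained one and none turned; 9 midpoint values had no test under an alternative. The losses were 25 of Cdk2, 11 of Hsp27, 9 of bin, 6 of ImpL1, 4 of mid, 3 each of Col4a1 and dpn and 2 each of htl and uif, all in the null, and 1 each of 11 other results, rols and CAP among them. Of all losses 17 came under the module block.

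The labels do not say what a replicate number marks. In the run records it equals the hybridisation day for all 16 arrays outside 65, so it is tied to that batch, and 17 of 20 arrays were closest to their own number. Of 40 pairs with the same number, 11 had deviations that correlated above 0.1, with a range of -0.0192 to 0.173 and a median of 0.126 for number 4, so the numbers were not treated as pairs. With the number as a replicate block no count moved by more than 1.5 times. The counts were 1883 for the null, 733 for 113, 1037 for 424, 599 for 65, 465, 750 and 1473 for the steps, 878 for the trend and 376, 446 and 448 for the midpoint, and 2, 2, 3 and 0 lists were called in null, 113, 424 and 65. Signals near background limit the low end, since the lowest signals in the null and hypomorphs lie below the pseudocount of 16.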

Other observations

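The share of 65 in the change, the day block and sarcomere tests of the last step, and the age test for 424 were chosen after the result was seen, and so were the genes of the next 2 paragraphs. The control stock carries visible mutations on the second chromosome, and some of the genes behind them were measured, as was pr, an eye pigment gene of the same chromosome that is not among those markers. The signal of pr was 277 ± 14.5 in the control and 55.7 ± 9.70 in the null (n = 4 each), a log2 change of -2.04 (limma, Benjamini-Hochberg adjusted p = 8.65e-14), and in 424 it changed by -0.30 (limma adjusted p = 0.0485). The wing vein gene px rose by 0.69 in the null (limma adjusted p = 6.16e-07), the apical matrix gene dpy fell by 0.55 (limma adjusted p = 0.0116), and cn, another eye pigment gene, was at 0.03 (limma adjusted p = 0.961).

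A few genes differed widely between alleles by their mean signals. Drsl5 had a signal of 7.63 in the control and 8.13 in the null, and of 1007 to 1640 in the 3 hypomorphs. CG3734 was at 6.28 in the control and 148 in 113. ImpE2 was low in 424 alone by its mean, at 51.9 against 608 to 834 elsewhere, and Tep4 in 65 alone, at 69.8 against 513 to 603. The myosin chaperone gene unc-45 was lower by nearly the same amount in every mutant, at -0.69 in 65, -0.74 in 424 and -0.77 in both 113 and the null.

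Other splits of the arrays rarely gave as many genes. Of the 35 splits of 8 arrays, 1, the real one, gave as many genes for each allele against the control and for each step. This argues against a random assignment of these arrays to groups as the source of the counts. It cannot exclude chance differences between pools or, for the hypomorphs, between fluidics modules. The other splits also mix genotypes, which widens the spread within their groups and lowers their counts. The real counts and the highest of the other splits were 1657 and 3 for the null, 617 and 1 for 113, 849 and 2 for 424, 507 and 1 for 65, 385 and 1, 606 and 1, and 1268 and 2 for the steps. For the trend, 1 of 100 splits gave as many genes, with 872 against 172. For the midpoint it was 1 of 100 each, with 324 against 96 in 113, 397 against 77 in 424 and 400 against 76 in 65. The genes lower in the null were chosen anew in each of these splits, so the number that could be placed was not held at the real 916. The midpoint comparison therefore decides nothing. A random assignment was not argued against for the number of called lists. There 13 of 35 splits gave at least the 2 lists of the null (highest other 3) and 9 at least the 2 of 113 (highest other 3). At least the 4 of 424 came from 3 splits (highest other 5). In 65 the real count was 0, which every split reaches, so the comparison decides nothing there (highest other 4). For the sarcomere list itself, the camera p was 1.00e-14 in the null and 7.62e-08 in the lowest other split, and in 424 it was 2.74e-05 with 1 other split lower, at 1.40e-05.

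The step from 113 to the null called 1268 genes, the most of the 3 steps. Both genotypes had 1 array on each of the 4 hybridisation days, so a shift common to the arrays of a day cancels in this difference by design, and the 1410 genes called with the day as a block test nothing further. Second-chromosome genes were over-represented (Fisher's exact odds ratio 1.625, 95% interval 1.44 to 1.84), so differences linked to that chromosome are a candidate explanation for part of the genes, as the labels do not say that the null arose in the control stock. For the sarcomere list, of which 8 of 17 members fell, lower Mef2 activity stays open as well: the test of that count (one-sided Fisher's exact p = 2.83e-05) was chosen after the falls were counted and decides nothing. How many genes belong to each stays open.

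The 164 genes that changed alike in all 4 mutants formed a second pattern. With the control arrays split into pairs and the alleles divided between them, 71 to 78 such genes remained. This argues against a deviation confined to either control pair as the whole cause. Alleles still shared each pair, so how much shared control arrays add stays open. Simulation gave 0, but data without any change yield few calls at all, so that 0 decides nothing here. The fluidics module stays open as a cause. Null arrays on the control's module lay nearer to the control by a median share of only 0.00164 (quartiles -0.133 and 0.0862). In the null, the changes were thus about as large on the control's module as on the other. These genes had to be called in the null, however. A gene that followed the module would split the null arrays and tend to miss that call, so a low share was largely built in. No hypomorph array ran on the control's module, so the share does not test the changes in the hypomorphs. The change in 65 was a median 0.926 of the mean change in 113 and null (quartiles 0.744 and 1.16). In the 12 sarcomere genes lower in the null this share had a median of 0.131, a lowest value of -2.21 and a highest of 0.46. These 12 were not all graded, as Act87E and Act79B moved the other way in 65. The higher share goes against a response like that of the 12, but this stays open. The 164 genes were selected for a call in 65 and include the graded falls of Mlc2, Mlc1 and TpnC73F. Differences on chromosomes other than the second, between the control stock and the mutant stocks, are a candidate explanation, since second-chromosome genes were rare (odds ratio 0.222, 95% interval 0.131 to 0.357). A response to mef2 already complete at the level of 65 was not tested and stays open too.

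The last pattern was 254 genes that moved at 424 and back at 113, 170 of them lower in 424, where independent calls give 14.5 and part of the excess may come from the 424 arrays that both steps share. The day, which is balanced between 424 and 113 and not between 65 and 424, is argued against as the whole cause, since 233 such genes were called with it as a block, of which 218 were shared, and so are differences linked to the second chromosome (odds ratio 0.613, 95% interval 0.457 to 0.815). Younger embryos in the 424 pools would lower sarcomere genes and raise cell cycle genes in 424 against the average of 65 and 113, and the 2 lists point opposite ways: sarcomere members were higher by a median of 0.0936 (quartiles 0.0246 and 0.184), which goes against it, and cell cycle members higher by 0.146, which goes with it. Other lists deviated as well, with medians of -0.129 for epidermis and cuticle, -0.146 for the ecdysone response, -0.381 for heat shock and 0.0801 for apoptosis. No prediction was written for these. The age of the pools stays open, since sarcomere genes also follow the allele. The level that 424 would have at equal age is not known to be that average. Differences between the lines on other chromosomes stay open. The fluidics module was not tested for these genes and stays open too. The 424 arrays ran on modules 1 and 2, while 65 and 113 also had arrays on module 3. With the module as a block, 202 of the 385 calls from 65 to 424 remained, and 289 of the 606 from 424 to 113. All kept their sign there, at standard errors 1.15-fold as large.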
